A study of Mus musculus with 9 samples.

How the data were processed

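RNA of NIH/3T3 cells, a mouse embryonic fibroblast line, was sequenced in 9 libraries: 3 from control cells, 3 from cells given UVA at 10 J/cm2, and 3 from cells given the same UVA dose and alpha-arbutin, a glycosylated hydroquinone. The treatment labels do not state whether alpha-arbutin was given before, during or after UVA. Groups were taken from the sample titles and treatment labels; the titles of the UVA samples read MOCK, and their treatment label gives the UVA dose. The control columns of the table carry the prefix NC, which was assigned to the control titles because the other column prefixes match the other titles by name. Per the labels' protocols, cells were kept in DMEM with fetal bovine serum, RNA was extracted with the TransZol Up Plus kit, and libraries were made from 2 ug of total RNA with the VAHTS Universal V8 RNA-seq kit. The alpha-arbutin dose, the time between treatment and harvest, and whether the libraries come from separate cultures are not given in the sources used here. Nor are the strandedness of the counting, the selection or depletion used to enrich the RNA, and the annotation release.

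Per the file headers, the authors' table gives a raw count and an FPKM value for each of 56691 Ensembl genes in each library, with gene coordinates and exonic sizes. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 1.9.1, HISAT2 2.2.1, HTSeq 0.6.1 and the mouse genome build mm39, with no role given for any of them. From the values, the deposited FPKM equals the deposited count divided by the exonic size and by the library's total count over all genes in the table: 510219 of 510219 values matched within 0.01. Coordinates are given as in the table, on mm39.

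Total counts per library, in units of 1e6, ran from 16.3 to 20.86, with 21026 to 21815 genes above 0. The 10 most abundant genes took 6.37 to 6.86% of the counts. Genes without a symbol (2639) held 0.112 to 0.118% of the counts and were kept. Intervals on ratios of few counts cover counting error only.

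The choices described here, including the gene lists, were made before the data were examined unless stated otherwise. The plan was limma on log2(FPKM + 1), or edgeR if the table also held counts. It does, so genes were tested with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood fit and F-test, two-sided) in R 4.3.3, with all 9 libraries in a fit on group alone. Of the 56691 genes, 14151 passed the filter. TMM factors ran from 0.992 to 1.007. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes, separately in each of 3 comparisons: UVA against control, co-treated against UVA, and co-treated against control. All adjusted p-values of genes are from this edgeR test unless another tool is named. Levels per gene are TMM-scaled counts per 1e6 counts (CPM), log2 fold changes carry the standard error of the fit, and intervals are 95%. The table of genes changed by UVA was crossed with that of the co-treated against UVA comparison to count genes moved back. Because both comparisons use the same UVA libraries, the crossing was repeated on 20 simulated count tables without any treatment effect and on 20 with the UVA effect only.

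Gene lists were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the 40 lists with at least 3 tested members, and again with the correlation estimated from the data. Camera compares a list with other genes. The test fry of limma, which asks whether a list's genes move on balance in 1 direction, was added to the plan and is named where its values are given. Counts of members called are given over all tested genes and, where they differ, adjusted over the list alone. The lists cover collagens, collagen processing, matrix proteases, protease inhibitors, other matrix proteins, the TGF-beta pathway, YAP targets, actin cytoskeleton genes regulated by SRF, base excision repair, nucleotide excision repair, mismatch repair, homologous recombination, end joining, the union of these repair lists, the damage checkpoint, p53 targets, NRF2 targets, antioxidant enzymes, metallothioneins, ATF4 targets, ER chaperones, heat shock, immediate early genes, inflammatory genes, interferon genes, mitosis, DNA replication, apoptosis, autophagy and lysosome, cholesterol synthesis, glycolysis and hypoxia, the mitochondrial genome, the cytosolic ribosome, nuclear retained RNA, the circadian clock, pigmentation, and markers of fibroblasts, adipocytes, muscle, epithelium, endothelium and immune cells. Genes named in the text are the 8 largest increases and 8 largest decreases among called genes whose groups do not overlap, up to 4 members of each list with the smallest p, and Col1a1, Col1a2, Col3a1, Mmp3, Mmp13, Timp1, Ogg1, Xpc, Cdkn1a, Gadd45a and Hmox1; genes without a symbol or with a provisional symbol were passed over. Only part of the genes under this rule are described; the results of the others are not reported here. Principal components were computed on log2 CPM of the tested genes.

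The edgeR step was tested on simulated counts with known changes in 200 of the 14151 genes, drawn from the real means, dispersions and library sizes. For co-treated against UVA, 48% of 50 genes changed 1.25-fold, 68% of those changed 1.5-fold, 86% of those changed 2-fold and 98% of those changed 4-fold were called. For UVA against control the shares were 48, 78, 88 and 96%, and for co-treated against control 50, 76, 84 and 96%. The simulation for co-treated against UVA called 158 genes, against 5 in the data. Fewer calls make the adjusted threshold stricter, so its shares are too high for the data. Camera was run on a separate simulated table with 40 lists of 24 genes. It called the 1 raised list and 0 unchanged ones. Genes varied independently in all these tables, so correlation between genes and differences shared within a library were not tested.

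Alternatives were no filter on low counts, a mean FPKM of at least 5, median-of-ratios size factors, only the compared groups in the fit, the replicate number as a block, leaving out each library, DESeq2 1.42.0, a minimum absolute log2 fold change of 1 and, starting from limma on log2(FPKM + 1), a pseudocount of 0.1, rescaling to TPM, quantile normalization and no variance trend. Transcript GC content for a check of technical trends came from the GENCODE M21 annotation on GRCm38, matched by gene identifier; no coordinates were taken from it.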

Results

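The data are counts per gene from RNA sequencing of NIH/3T3 mouse embryonic fibroblasts in 3 groups of 3 libraries: control cells, cells irradiated with UVA at 10 J/cm2, and cells given the same dose and alpha-arbutin (called co-treated cells, whatever the order). The study asks whether alpha-arbutin counters photodamage, with DNA repair and collagen synthesis named in particular. Total counts, in units of 1e6, were 17.11, 17.72 and 20.86 in the control libraries. They were 18.24, 16.3 and 20.06 in the UVA libraries and 16.4, 17.27 and 18.16 in the co-treated libraries. Mitochondrially encoded genes held 3.61% ± 0.0996 of counts in control, 3.88% ± 0.0111 in UVA and 3.88% ± 0.127 in co-treated libraries (SD, n = 3). Fibroblast markers summed to 7333 CPM in control and 7668 CPM in UVA cells. Markers of most other cell types were low: immune markers summed to 23.1 and 27.0 CPM, endothelial markers to 6.51 and 7.42, epithelial markers to 1.94 and 3.08, and muscle markers to 3.47 and 7.32. The pigmentation list stood higher, at 331 and 546 CPM, mostly from Gpnmb (318 and 541 CPM), a lysosomal glycoprotein gene that is not restricted to pigment cells.

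The first principal component, with 38.7% of the variance, placed the control libraries at -28.8 ± 0.524, the UVA libraries at 15.5 ± 4.60 and the co-treated libraries at 13.3 ± 4.60 (SD, n = 3). The difference between UVA and co-treated cells on this axis was within the spread between libraries (exact two-sided permutation p = 0.7; 3 against 3 cannot go below 0.1). On the second component, with 10.0% of the variance, UVA and co-treated libraries did not overlap, while UVA and control libraries did: UVA libraries lay at -10.2 ± 11.9, co-treated libraries at 10.8 ± 4.11 and control libraries at -0.563 ± 2.39 (SD, n = 3). The exact p there was 0.1, the smallest possible, in a test added after the scores were seen.

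**Figure D1:**
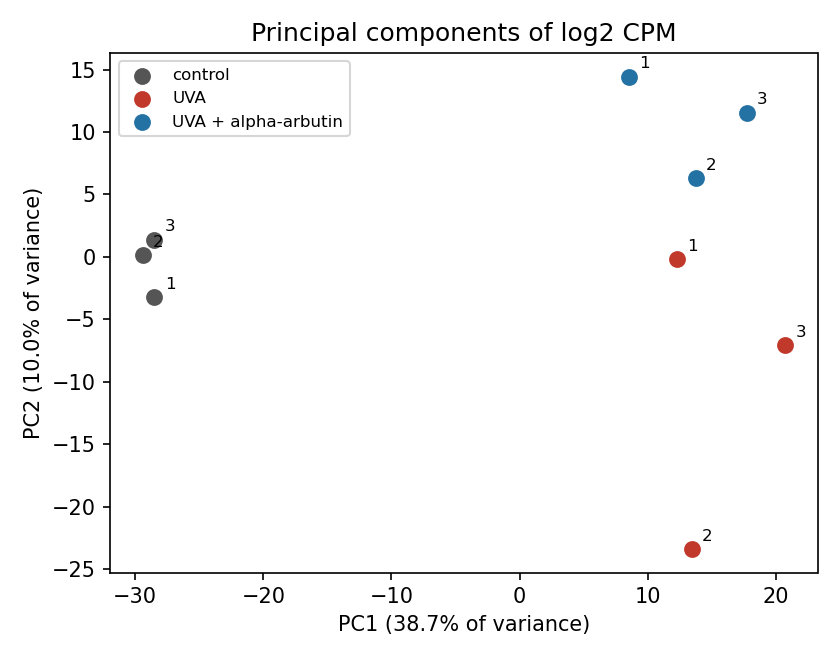
Scores of the 9 libraries on the first (38.7% of variance) and second (10.0%) principal components of log2 CPM, coloured by group and numbered by replicate. The control libraries sit near -28.8 on the first component, and both irradiated groups lie on the other side of 0.

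The comparison of UVA with control cells shows how irradiated cells without alpha-arbutin differed from control cells. The control titles do not say whether those cells had a mock treatment. Genes for the fibrillar collagens fell strongly. Col1a1, which encodes the main chain of type I collagen (ENSMUSG00000001506, chromosome 11, 94827050 to 94843868 on mm39), went from 957 ± 16.1 CPM in control to 293 ± 38.3 CPM in UVA cells (SD, n = 3), a log2 fold change of -1.71 ± 0.07 (SE; 95% interval -1.86 to -1.56; adjusted p = 1.92e-16). Col1a2, the partner chain, had a log2 fold change of -1.19 ± 0.07 (adjusted p = 4.01e-14), and Col3a1, which encodes type III collagen (ENSMUSG00000026043, chromosome 1, 45350698 to 45388866), of -1.39 ± 0.05 (adjusted p = 5.15e-17). Of 17 tested collagen genes, 12 fell and 2, the basement membrane genes Col4a1 and Col4a2, rose. The list's median was -0.80 (camera adjusted p = 1.19e-26, and adjusted p = 0.0156 with an estimated correlation). Col4a1 and Col4a2 lie head to head with overlapping ends, and their reads there cannot be assigned without strand.

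Genes that process collagen fell with it: 13 of 23 were lower and 2 higher (14 lower when adjusted over the list alone), with a list adjusted p of 1.85e-10 (adjusted p = 0.0309 with an estimated correlation). They included Adamts2, the procollagen N-proteinase, at -1.93 ± 0.08, the crosslinking enzymes Lox at -1.20 ± 0.07 and Loxl1 at -0.94 ± 0.05, and the prolyl hydroxylase subunit P4ha1 at -0.71 ± 0.05. Of 20 other matrix proteins, 14 fell and 0 rose, among them Fbn1 at -1.42 ± 0.07, Fbln5 at -1.47 ± 0.09, Bgn at -0.65 ± 0.04 and Fn1 at -0.61 ± 0.04 (list adjusted p = 2.06e-19, and adjusted p = 0.0247 with an estimated correlation). Matrix proteases also fell as a list, with 7 of 11 lower and 3 higher (8 lower adjusted over the list alone; adjusted p = 0.00103, but adjusted p = 0.0522 with an estimated correlation). Adamts5 was at -1.08 ± 0.07, Mmp2 at -0.44 ± 0.04 and Adamts1 at -0.53 ± 0.05, while the lysosomal protease gene Ctsl rose at 0.34 ± 0.04. Mmp3, the stromelysin gene, rose by a log2 fold change of 0.47 ± 0.17 (adjusted p = 0.0367), a call that ended without control replicate 2 (adjusted p = 0.104) or 3 (0.234), without UVA replicate 1 (0.0931) or 3 (0.164), and with DESeq2 (0.0599). Mmp13 had too few counts to be tested. Among 8 protease inhibitors 5 fell and 2 rose, with Serpinf1 at -0.53 ± 0.04 and Timp1, an inhibitor of matrix metalloproteinases, at 0.45 ± 0.08 (list adjusted p = 0.0189, but adjusted p = 0.226 with an estimated correlation). The Timp1 gene overlaps Syn1 on the other strand.

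**Figure D2:**
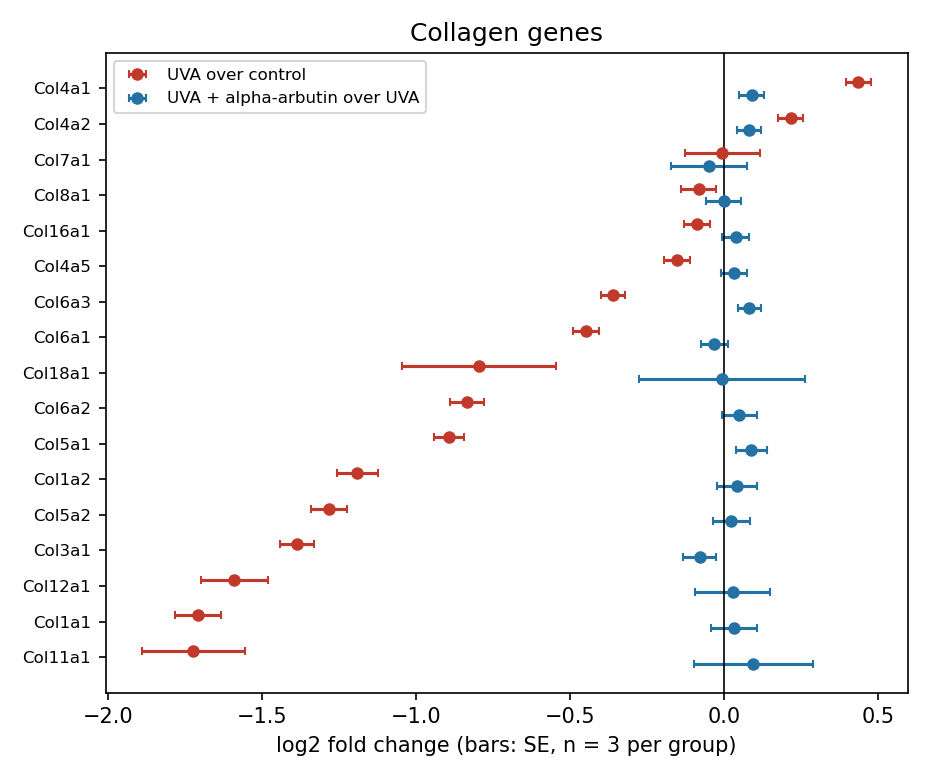
Log2 fold changes of the 17 tested collagen genes in UVA over control cells (red) and co-treated over UVA cells (blue); points are edgeR estimates and bars their SE, with 3 libraries per group. Col1a1 lies at -1.71 in the first comparison and at 0.03 in the second.

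Contractile and identity genes of fibroblasts changed with the matrix. Acta2, smooth muscle actin, fell by 2.43 ± 0.12 on the log2 scale (adjusted p = 2.45e-15), and 6 of 12 actin cytoskeleton genes regulated by SRF were lower and 1 higher (7 and 3 adjusted over the list alone; list adjusted p = 0.000374, but adjusted p = 0.303 with an estimated correlation). YAP targets were lower in 8 of 14 cases, with the tissue factor gene F3 at -1.30 ± 0.10 (list adjusted p = 0.00152, but adjusted p = 0.387 with an estimated correlation). Of 11 fibroblast markers 6 fell, including Thy1 at -1.17 ± 0.09 and Pdgfra at -0.72 ± 0.05, and 2 rose, Vim at 0.40 ± 0.04 and Cd44 at 0.39 ± 0.04 (list adjusted p = 0.0183, but adjusted p = 0.123 with an estimated correlation). The 3 tested adipocyte markers fell as a list (adjusted p = 0.000172, but adjusted p = 0.0522 with an estimated correlation), with Lpl, lipoprotein lipase, at -1.11 ± 0.09; the list summed to 41.3 CPM in control and 18.8 CPM in UVA cells.

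DNA repair genes did not differ from other genes as a list by camera, but were lower by fry, which tests a list against no change. Of 116 tested members of the 5 repair lists, 9 were higher and 14 lower (7 and 14 adjusted over the list alone), with a median of -0.06 and a camera adjusted p of 0.451; at an unadjusted p under 0.05, 12 were higher and 25 lower. The fry adjusted p was 0.00568. Ercc1, a subunit of the nuclease that cuts 5' of bulky lesions (ENSMUSG00000003549, chromosome 7, 19078703 to 19090449), nearly doubled from 50.3 ± 1.92 to 95.7 ± 11.7 CPM (SD, n = 3), a log2 fold change of 0.93 ± 0.07 (adjusted p = 5.77e-12). It overlaps Cd3eap on the other strand, whose log2 fold change was 0.05 ± 0.08. Nbn, part of the MRN complex at double-strand breaks, rose at 0.39 ± 0.07, whereas Rad51c fell at -0.53 ± 0.11, Fancg at -0.74 ± 0.16 and the oxidised-base glycosylase gene Neil1 at -0.55 ± 0.15. Ogg1, the 8-oxoguanine glycosylase, was at 0.01 ± 0.09 (95% interval -0.18 to 0.21) and Xpc, a sensor of helix distortion, at 0.07 ± 0.08 (-0.09 to 0.23); neither passed. By pathway, camera adjusted p was 0.365 for base excision repair, 0.522 for nucleotide excision repair, 0.496 for mismatch repair, 0.495 for homologous recombination, 0.414 for end joining and 0.469 for the damage checkpoint, where 3 of 21 genes rose (2 adjusted over the list alone). By fry, base excision repair (adjusted p = 0.018), mismatch repair (0.0237), homologous recombination (0.0204) and end joining (0.00126) were lower and the damage checkpoint higher (0.0272), while nucleotide excision repair did not pass (0.136). In this comparison 32 of the 40 lists passed by fry.

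Targets of p53 rose as a list, with 10 of 24 higher and 4 lower (11 higher adjusted over the list alone; list adjusted p = 6.51e-05, and adjusted p = 0.0311 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, had a log2 fold change of 0.98 ± 0.07 (adjusted p = 1.89e-11), Mdm2 of 0.86 ± 0.06, Eda2r of 0.91 ± 0.08 and Ccng1 of 0.64 ± 0.05. Gadd45a went the other way at -0.77 ± 0.11 (adjusted p = 1.45e-06).

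Several stress programmes shifted as well. Immediate early genes were higher in 15 of 22 cases and lower in 3 (16 and 4 adjusted over the list alone), led by the phosphatase genes Dusp6 at 0.95 ± 0.06 and Dusp5 at 0.84 ± 0.09. The list's adjusted p was 6.77e-05 (but adjusted p = 0.171 with an estimated correlation). Heat shock genes were higher in 9 of 14 cases (10 adjusted over the list alone), with Cryab at 0.72 ± 0.05 and Hspa1b, which shares reads with its near-identical neighbour Hspa1a, at 0.74 ± 0.16 (list adjusted p = 6.51e-05, but adjusted p = 0.185 with an estimated correlation). The metallothionein list rose in all 3 tested members, Mt1, Mt2 and the zinc exporter gene Slc30a1 (adjusted p = 0.00181, but adjusted p = 0.0949 with an estimated correlation). Of 20 antioxidant enzymes 7 rose and 2 fell (9 and 2 adjusted over the list alone), with Gpx1, a glutathione peroxidase, at 1.03 ± 0.09 and Prdx3 at -0.33 ± 0.05 (list adjusted p = 0.00998, but adjusted p = 0.0949 with an estimated correlation). Targets of NRF2, the transcription factor of the oxidative stress response, were split: 13 of 24 rose and 4 fell, with Prdx1 at 0.37 ± 0.04 against Slc7a11, the cystine transporter, at -0.50 ± 0.08 (list adjusted p = 0.0233, but adjusted p = 0.489 with an estimated correlation). Hmox1, haem oxygenase 1, was lower at -0.24 ± 0.08 (adjusted p = 0.0306), a call that ended without control replicate 1 (adjusted p = 0.083) or 3 (0.177) and without UVA replicate 1 (0.105) or 3 (0.0961).

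Transcripts of ATF4 targets and of the glycolysis and hypoxia list were lower. ATF4 targets were lower in 17 of 19 cases, including the folate enzyme gene Aldh1l2 at -0.81 ± 0.05, the amino acid transporter gene Slc7a5 at -0.62 ± 0.06 and asparagine synthetase, Asns, at -0.44 ± 0.04 (list adjusted p = 6.23e-14, but adjusted p = 0.138 with an estimated correlation); Aldh1l2 overlaps Nopchap1 on the other strand. Glycolysis and hypoxia genes were lower in 14 of 24 cases (15 adjusted over the list alone), with Pdk1 at -1.10 ± 0.06, Bnip3 at -1.28 ± 0.09 and Pfkl at -0.68 ± 0.05 (list adjusted p = 5.41e-11, and adjusted p = 0.0347 with an estimated correlation). ER chaperones shifted less (7 of 18 lower, 3 higher; list adjusted p = 0.0491, but adjusted p = 0.226 with an estimated correlation). Autophagy and lysosome genes were higher in 8 of 23 cases and lower in 3 (adjusted p = 0.0303, but adjusted p = 0.487 with an estimated correlation). The mitochondrial genome was higher in 6 of 13 cases (adjusted p = 0.0303, but adjusted p = 0.494 with an estimated correlation). Cytosolic ribosome genes were higher in 22 of 31 cases by a median of 0.12 (adjusted p = 0.000459, but adjusted p = 0.489 with an estimated correlation). The remaining lists had an adjusted p between 0.058 and 0.981. They were DNA replication, mitosis, apoptosis, inflammatory and interferon genes, the TGF-beta pathway, cholesterol synthesis, nuclear retained RNA, the circadian clock, pigmentation, and endothelial and immune markers. Muscle and epithelial markers had too few tested members. Median, mean and test differed in sign for interferon genes (median -0.06, mean 0.09), nuclear retained RNA (0.06 and -0.08), pigmentation (median -0.33, test up) and immune markers (0.46 and -0.39). Within them Tgfbr2 fell at -0.72 ± 0.06, the clock output gene Hlf at -1.90 ± 0.13 and Csf1 at -0.63 ± 0.05, and Nfkbia rose at 0.64 ± 0.07.

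In all, 4142 of 14151 tested genes were called, 2078 higher and 2064 lower, 388 of them with an absolute log2 fold change of at least 1. The groups did not overlap in 42.0% of genes, against 10% by chance. The largest increases were Prl2c3, a prolactin family gene with near-identical copies, at 3.44 ± 0.11 (13.5 ± 2.37 to 147 ± 29.2 CPM, SD, n = 3), Itprid1 at 3.44 ± 0.59, Cyp2ab1 at 3.26 ± 0.66, Ceacam1 at 3.15 ± 0.61, Pls1 at 2.89 ± 0.54, the histone gene H3c4 at 2.83 ± 0.64, Fer1l6 at 2.73 ± 0.35 and Tmprss11b at 2.72 ± 0.46. The largest decreases included Prelp at -3.51 ± 0.60, Nyap2 at -3.15 ± 0.70, Igf1 at -2.91 ± 0.34, Ptprc at -2.82 ± 0.60, Rtl3 at -2.74 ± 0.52, and Ogn, the leucine-rich matrix protein osteoglycin, at -2.78 ± 0.15 (35.6 ± 1.36 to 5.22 ± 1.16 CPM, SD, n = 3). Igf2 had 39 counts in the control libraries and 1 in the UVA libraries, a ratio of 37.8 (95% counting interval 6.40 to 1532), and Sema3c 41 and 3, a ratio of 13.3 (4.23 to 66.9). Many of these rest on few counts: H3c4 had 7 in the control and 51 in the UVA libraries, Tmprss11b 12 and 78, Itprid1 9 and 100, Ceacam1 8 and 73, Pls1 7 and 53, Cyp2ab1 6 and 59, Prelp 63 and 5, Nyap2 40 and 4, and Ptprc 54 and 7. With 1 library left out, log2 fold changes ran from 2.40 to 4.01 for H3c4, 2.32 to 3.57 for Tmprss11b, 2.56 to 3.84 for Ceacam1, 2.78 to 3.90 for Itprid1, -4.44 to -2.54 for Nyap2 and -3.41 to -2.19 for Ptprc. They ran from -6.66 to -4.28 for Igf2, -4.43 to -3.11 for Sema3c and -4.11 to -3.27 for Prelp. Ogn, Igf2 and Ceacam1 overlap genes on the other strand.

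With values rescaled to TPM and tested by limma, the split was 1102 higher and 2128 lower, and under quantile normalization the cytosolic ribosome list no longer passed (adjusted p = 0.664). Some list calls ended without a single library. These were NRF2 targets (adjusted p = 0.0818 without control replicate 2, 0.08 without UVA replicate 3), ER chaperones (0.0543 and 0.067 without control replicates 1 and 2, 0.115 without UVA replicate 1), autophagy and lysosome genes (0.0556 without control replicate 2, 0.0944 without UVA replicate 3) and the mitochondrial genome (0.0987 without control replicate 1). DNA replication passed without UVA replicate 1 (0.0408).

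**Figure D3:**
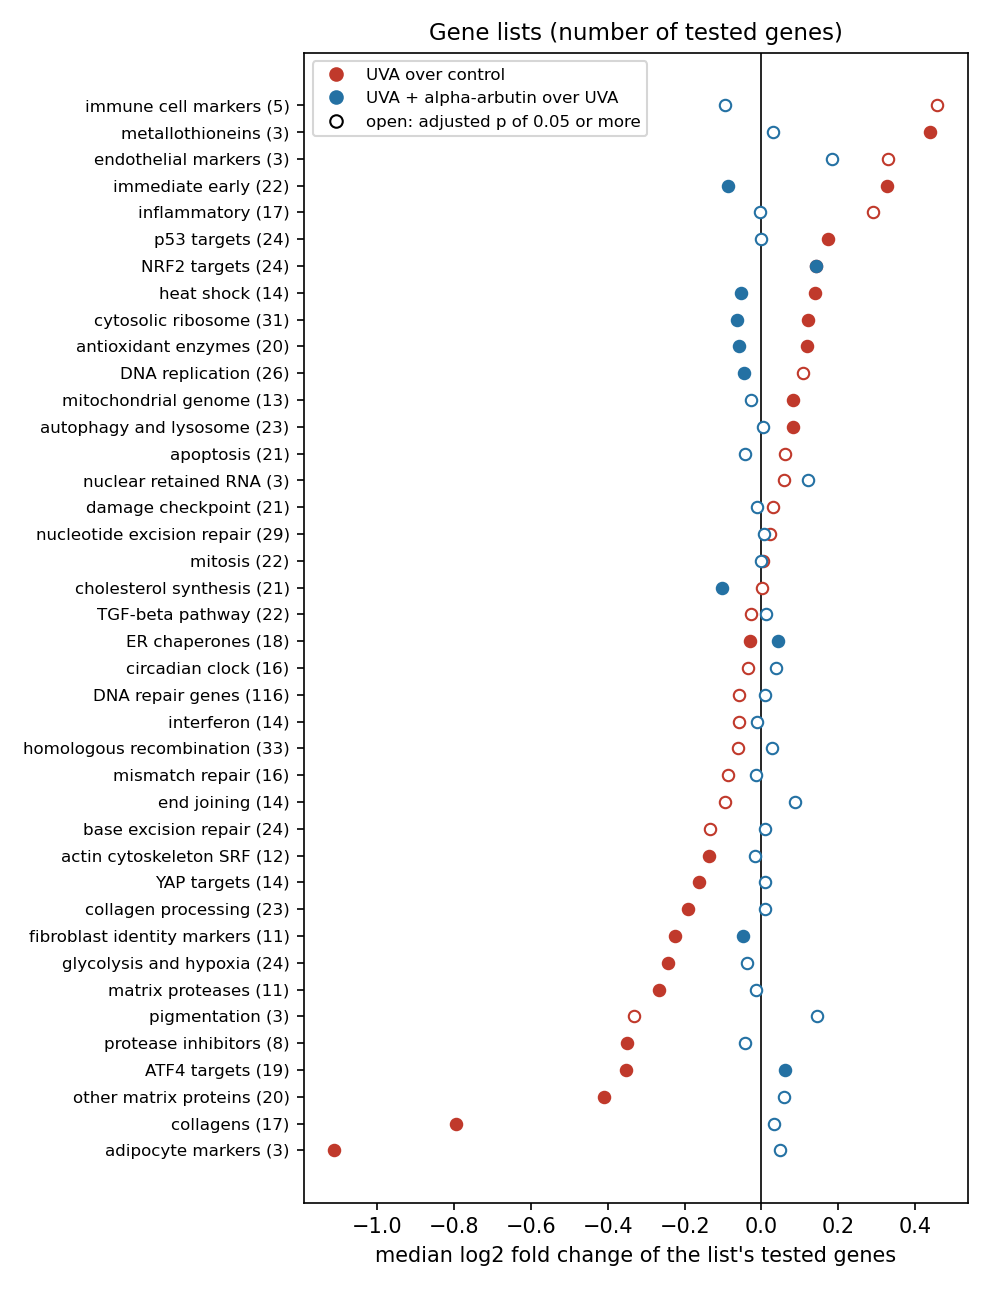
Median log2 fold change of each gene list in UVA over control (red) and co-treated over UVA cells (blue), with the number of tested genes in brackets; filled points have a camera adjusted p below 0.05 at the preset correlation. Collagens lie at -0.80 and 0.03; NRF2 targets lie at 0.14 in both, so that the points coincide.

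The comparison of co-treated with UVA cells sets irradiated cells with alpha-arbutin against irradiated cells without it. With alpha-arbutin 4 genes rose, by less than 1.5-fold each: Slc7a11, Hmox1, Txnrd1 and Slc48a1. Slc7a11, which imports cystine for glutathione synthesis (ENSMUSG00000027737, chromosome 3, 49846975 to 50398063), was at 42.4 ± 3.85 CPM in UVA and 62.0 ± 8.24 CPM in co-treated cells (SD, n = 3), a log2 fold change of 0.55 ± 0.08 (95% interval 0.39 to 0.71; adjusted p = 0.00102). Hmox1 (ENSMUSG00000005413, chromosome 8, 75820249 to 75827217) rose from 20.9 ± 1.36 to 28.8 ± 0.712 CPM, at 0.46 ± 0.08 (adjusted p = 0.0153). Txnrd1, thioredoxin reductase 1 (ENSMUSG00000020250, chromosome 10, 82669785 to 82733546), rose at 0.25 ± 0.04 (adjusted p = 0.00327), and the haem transporter gene Slc48a1 (ENSMUSG00000081534, chromosome 15, 97676401 to 97690573) at 0.27 ± 0.04 (adjusted p = 0.00684); the overlapping Hdac7 on the other strand was at 0.02 ± 0.05. Rn7sk, the small nuclear RNA 7SK (ENSMUSG00002076161, chromosome 9, 78082585 to 78082915), which has many near-identical copies, fell at -0.93 ± 0.16 (adjusted p = 0.00684), with 153, 125 and 164 counts in the UVA and 73, 74 and 74 in the co-treated libraries. For each of these genes the UVA and co-treated libraries did not overlap. 7SK has no poly(A) tail, and the summed level of such RNAs, 7SK included, was also lower, as given under the other observations.

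**Figure D4:**
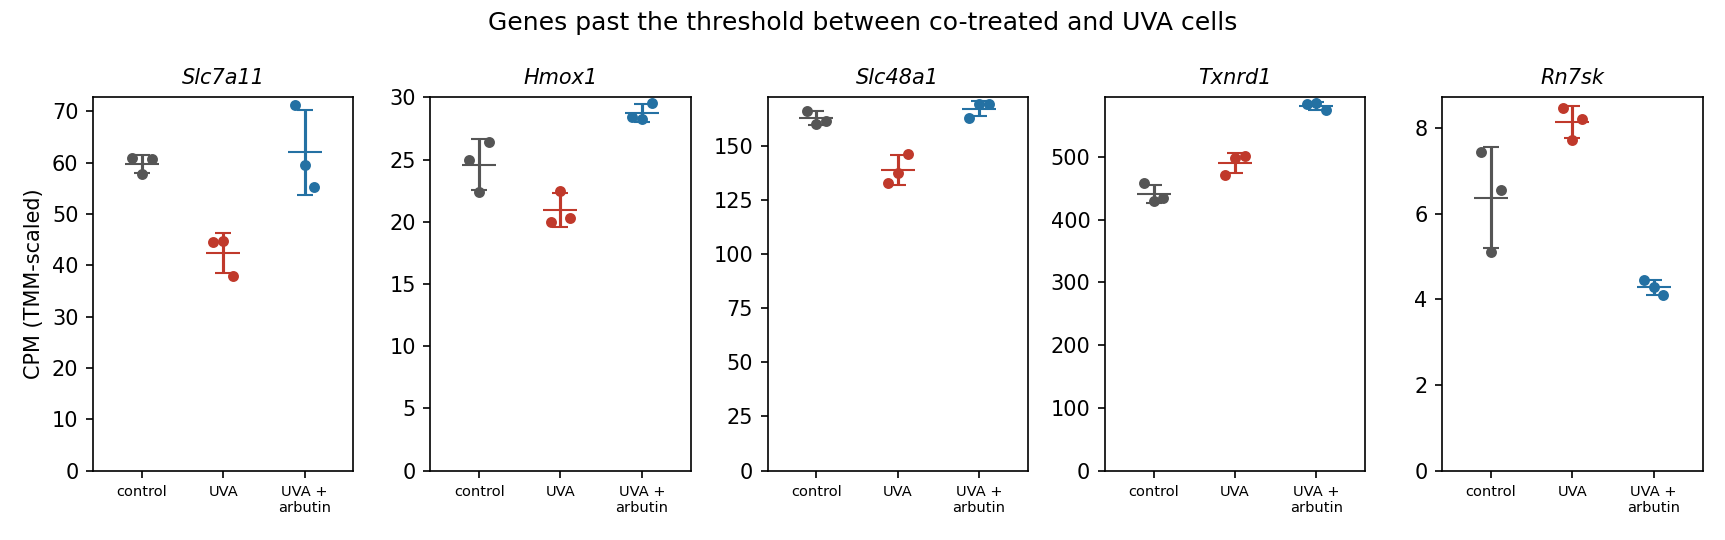
CPM of the 5 genes called between co-treated and UVA cells in each library (points), with the mean and SD of each group of 3 (lines); each vertical axis starts at 0. Slc7a11 averages 42.4 CPM in UVA and 62.0 CPM in co-treated cells.

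NRF2 targets were higher as a list: 22 of 24 had a positive log2 fold change, with a median of 0.14, and 3 were called (13 adjusted over the list alone). The list's adjusted p was 1.05e-23 at the preset correlation, but adjusted p = 0.169 with an estimated correlation; the fry adjusted p was 0.0498. Nqo1, a quinone reductase, was at 0.35 ± 0.08 (adjusted p = 0.123) and was called by DESeq2 (adjusted p = 0.0397). Cholesterol synthesis genes were lower as a list, with a median of -0.10 and 0 of 21 called (8 lower adjusted over the list alone, 10 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma; list adjusted p = 5.75e-09, but adjusted p = 0.434 with an estimated correlation). Mvk, mevalonate kinase, was at -0.24 ± 0.07 (adjusted p = 0.507). Cytosolic ribosome genes were lower with a median of -0.06 and 0 of 31 called (7 lower at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma; list adjusted p = 4.44e-09, but adjusted p = 0.434 with an estimated correlation), and not so under quantile normalization (adjusted p = 0.0618).

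The other lists past the threshold moved by small amounts. None of their members was called by the main edgeR fit, DESeq2 or limma on log2(FPKM + 1), and 5 or fewer per list had an unadjusted p under 0.05. This does not cover the alternative edgeR settings. Adjusted over the list alone, 1 ATF4 target was higher and 1 heat shock gene lower. ATF4 targets had a median of 0.06 (adjusted p = 0.000885, but adjusted p = 0.575 with an estimated correlation) and ER chaperones of 0.04 (0.0338, but adjusted p = 0.434 with an estimated correlation). Medians were -0.05 for heat shock genes (adjusted p = 0.00228), -0.09 for immediate early genes (0.0034), -0.04 for DNA replication (0.00228), -0.06 for antioxidant enzymes (0.0219, with 5 of 20 positive; fry adjusted p = 0.039) and -0.05 for fibroblast markers (0.0338). With an estimated correlation their adjusted p was 0.434, 0.434, 0.51, 0.417 and 0.417. With that correlation 0 of the 40 lists passed in this comparison. The UVA libraries are shared with the comparison of UVA with control. A chance shift in them moves a list in opposite directions in both, and this was not simulated for lists. The remaining 30 lists had an adjusted p between 0.161 and 0.997 at the preset one.

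Collagen genes showed no recovery that the test detected. EdgeR called 0 of 17, with 2 at an unadjusted p under 0.05, and DESeq2 and limma also called 0; the list's median was 0.03 (adjusted p = 0.208). Col1a1 stood at 293 ± 38.3 CPM in UVA and 299.7 ± 45.1 CPM in co-treated cells (SD, n = 3), a log2 fold change of 0.03 (95% interval -0.12 to 0.18), against a change of -1.71 with UVA. The intervals were -0.09 to 0.18 for Col1a2, -0.19 to 0.03 for Col3a1, -0.45 to 0.24 for Mmp3 and -0.25 to 0.06 for Timp1. Collagen processing genes (adjusted p = 0.788) and matrix proteases (0.699) did not pass.

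Nor did DNA repair genes pass: 0 of 116 were called by edgeR, DESeq2 or limma, with 7 higher and 1 lower at an unadjusted p under 0.05, and the list's median was 0.01 (camera adjusted p = 0.514, fry adjusted p = 0.355). Members with small p included Brca2 at 0.17 ± 0.06, Xrcc5 at 0.15 ± 0.06 and Ercc8 at 0.34 ± 0.14, with adjusted p from 0.627 to 0.686. Ogg1 had a 95% interval of -0.12 to 0.26, Xpc of -0.19 to 0.14, Cdkn1a of -0.19 to 0.10 and Gadd45a of -0.08 to 0.38. By pathway, adjusted p was 0.911 for base excision, 0.987 for nucleotide excision and 0.997 for mismatch repair, 0.342 for homologous recombination and 0.161 for end joining; p53 targets were at 0.699. By fry, end joining genes were higher (adjusted p = 0.0498), 1 of 3 lists that passed in this comparison, beside NRF2 targets and antioxidant enzymes.

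Of 14151 tested genes, 5 were called, 4 higher and 1 lower, 957 had an unadjusted p under 0.05, and the groups did not overlap in 10.8% of genes, against 10% by chance. The count moved with single libraries: it was 8 without UVA replicate 2, 22 without UVA replicate 3, 1 without co-treated replicate 2 (Slc7a11) and 2 without co-treated replicate 3 (Slc7a11 and Txnrd1), and went to 12 with DESeq2 and 0 with limma. Hmox1 and Slc48a1 also dropped out without UVA replicate 1 (adjusted p = 0.106 and 0.0557). Without single libraries the list calls for NRF2 targets, cholesterol synthesis and the cytosolic ribosome held. Each of the other 7 ended at least once, with an adjusted p up to 0.361 for DNA replication and 0.306 for ER chaperones. A split of the UVA and co-treated libraries that does not follow treatment also called cholesterol synthesis (camera adjusted p = 4.03e-16) and NRF2 targets (4.24e-11). NRF2 targets passed camera at the preset correlation in further such splits (adjusted p = 3.14e-07, 0.00025, 0.00161 and 0.0322). In the others they did not (0.257, 0.583, 0.998 and 0.769). Every such split keeps most libraries of a group together, so part of a real treatment difference would remain in it. The collagen list passed at a median of 0.07 without co-treated replicate 3 (adjusted p = 0.0152).

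The comparison of co-treated with control cells shows how far the co-treated cells stood from unirradiated ones. They kept the low collagen and high p53 target levels: Col1a1 was at -1.68 ± 0.07 (adjusted p = 4.71e-16), Col3a1 at -1.47 ± 0.05, Acta2 at -2.77 ± 0.12 and Cdkn1a at 0.94 ± 0.07. Collagens fell in 12 of 17 cases and rose in 2, with a median of -0.78 (list adjusted p = 6.51e-26, and adjusted p = 0.0125 with an estimated correlation). NRF2 targets were higher in 17 of 24 cases and lower in 0 (18 higher adjusted over the list alone), with a median of 0.25 (list adjusted p = 2.97e-10, but adjusted p = 0.12 with an estimated correlation). They included both subunits of glutamate-cysteine ligase, Gclm at 0.59 ± 0.06 and Gclc at 0.54 ± 0.06, the ferritin gene Fth1 at 0.44 ± 0.05, and Txnrd1 at 0.40 ± 0.04. DNA repair genes did not differ from other genes by camera (10 of 116 higher, 11 lower; 7 and 5 adjusted over the list alone; adjusted p = 0.63) but were lower by fry (adjusted p = 0.0365; 13 higher and 21 lower at an unadjusted p under 0.05), with Ercc1 again higher at 0.83 ± 0.07.

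In this comparison 3657 genes were called, 1834 higher and 1823 lower, 350 with an absolute log2 fold change of at least 1. The largest changes included Ceacam1 at 3.80 ± 0.58, Prl2c3 at 3.43 ± 0.11, Ccl20 at 2.88 ± 0.58, Ranbp3l at -3.29 ± 0.33 and Igf1 at -2.95 ± 0.34. Ceacam1 rests on 8 counts in the control and 108 in the co-treated libraries, with a log2 fold change from 3.26 to 4.48 with 1 library left out, and Ccl20 on 6 and 43. Igf2 had 39 counts in control and 1 in co-treated libraries, a ratio of 36.1 (95% counting interval 6.11 to 1461). All 18 lists called here were among the 21 called for UVA, in the same direction. With an estimated correlation 7 lists passed: collagens, collagen processing, matrix proteases, other matrix proteins, p53 targets, glycolysis and hypoxia, and fibroblast markers. The 3 lists called for UVA alone were the antioxidant enzymes, ER chaperones and cytosolic ribosome, whose difference between co-treated and UVA cells is given above. That difference was opposite to the UVA effect in each, which a chance shift in the shared UVA libraries would also give. Hmox1 was at 0.22 ± 0.08 (adjusted p = 0.0404), a call that ended without control replicate 1 (adjusted p = 0.0786) or 2 (0.22) and without co-treated replicate 1 (0.0617), 2 (0.0708) or 3 (0.124).

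Of the genes called in both comparisons with control, 2970 changed in the same direction and 1, Hmox1, in the opposite one. If the calls were independent, 269 shared increases and 266 shared decreases would be expected, but both comparisons use the same control libraries. Across genes, which are not independent replicates, the log2 fold changes had r = 0.838. This lay below the mean of 0.892 in 20 simulations with the UVA effect alone and above the mean of 0.496 in 20 without any effect. Of the 4142 genes called for UVA, 3 moved back with alpha-arbutin, Slc7a11, Hmox1 and Slc48a1, and Txnrd1 moved further from control. The sign of the alpha-arbutin effect was opposite to that of UVA in 70.4% of the 4142 genes, against 60.6% (59.9 to 61.9) in 20 simulations with the UVA effect alone, where at most 1 gene moved back. These simulations let genes vary independently, so differences between libraries in the extent of the whole UVA response are not in them, and 3 UVA libraries are too few to be divided between the comparisons. They also took the observed group means as true, so noise in those means entered the simulated UVA effect. With the UVA effect alone, its log2 fold changes had a mean variance of 0.199, against 0.175 in the data. A median of 4596 genes were called there, against 4142. The data's r and share of opposite signs are therefore not evenly matched with the simulated ones.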

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

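Limma on log2(FPKM + 1) was the planned test for a table without counts. Its use as an alternative beside edgeR was chosen only after the data were seen. The other alternatives were planned. Under the settings run, the collagen list kept its direction and its side of the threshold in UVA against control and in co-treated against control, though its median for UVA against control, -0.80, shrank to -0.465 at a mean FPKM of at least 5 and to -0.4545 with limma on log2(FPKM + 1), and for co-treated against control from -0.78 to -0.4885 and -0.4779. The DNA repair list passed camera under none in any of the 3 comparisons. The gene counts for UVA against control ran from 3213 to 3839 with 1 library left out, 3732 with DESeq2, and for co-treated against control from 2774 to 3491. Requiring an absolute log2 fold change of at least 1 left 388 and 350 genes, and 0 for co-treated against UVA, by construction. The count for co-treated against UVA, 5, was 29 without a filter on low counts, 19 with the replicate number as a block, 12 with DESeq2, and 0 with limma on log2(FPKM + 1), with a pseudocount of 0.1, after rescaling to TPM, after quantile normalization and without a variance trend; leaving out 1 library gave 1 to 22. The 5 genes were among the 29, the 19 and the 12. The 3 genes moved back became 13, 9, 8 and 0 under the same settings, 0 at the fold change minimum, and 1 to 5 with 1 library left out. Lists called for UVA against control, 21, were 13 at a mean FPKM of at least 5 (33 lists had enough members) and 5 with an estimated correlation. They were 14 with limma on log2(FPKM + 1), where 36 lists had enough members, and 13 with limma after quantile normalization. For co-treated against UVA, 10, they were 8 with limma on log2(FPKM + 1) and 6 with limma after quantile normalization. They were 0 with an estimated correlation there and 6 to 10 with 1 library left out. For co-treated against control, 18, they were 7 with an estimated correlation. The collagen median for co-treated against UVA lay between -0.0289 and 0.0722 with 1 library left out. Rplp0 in UVA against control, 0.16, became -0.0295 (adjusted p = 0.426) after quantile normalization. Apart from the fold change minimum, the cause was not tested. Of the values of named genes under alternatives, 7877 stayed on their side of the threshold, 278 lost it, 43 gained it and 1 called value reversed; for the other lists these counts were 1707, 136 and 14, and 0 called reversed. Values that did not pass could change sign: with Rplp0 included, signs of named genes differed in 8 values for UVA against control, 35 for co-treated against UVA and 5 for co-treated against control, and some uncalled list medians near 0 crossed it. The alternative with protein-coding genes alone was not run, as the table names no gene type. Depth limits genes such as Mmp13, with 47 counts over the 9 libraries.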

Other observations

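The tests of a low level in the UVA libraries, of S phase and of other splits for the NRF2 median, and the set of histone genes, were chosen only after the results were seen. The cutoff for the corrected NRF2 median was set from the fitted median, which was therefore known when the cutoff was written.

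Replication-dependent histone genes, which make transcripts that mostly end in a stem-loop without a poly(A) tail, were higher after UVA. Of 11 tested, 5 rose and 0 fell, with a median log2 fold change of 0.62. H2bc4 was at 2.65 ± 0.32 and H4c9 at 1.33 ± 0.39 in UVA against control cells. Summed over the family, histone counts stood at 15.3 ± 1.45 CPM in control, 25.3 ± 1.92 CPM in UVA and 17.1 ± 1.63 CPM in co-treated cells (SD, n = 3). In co-treated against UVA cells 10 of 11 had a negative log2 fold change, with a median of -0.57, and edgeR called 0. Other RNAs without a poly(A) tail, among them 7SK, summed to 29.6 ± 1.34, 30.8 ± 2.15 and 24.2 ± 1.09 CPM. In co-treated against UVA cells 4 of 14 tested ones had a positive log2 fold change, with a median of -0.31. Whether RNA selection differed between co-treated and UVA libraries was not tested.

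The fall of collagen genes after UVA was set against a trend with GC content and length. Log2 fold changes were corrected for transcript GC content, exonic length and gene span over the 13947 of 14151 tested genes with a GC value. The list's median was then -0.6856, against -0.80 before, with quartiles of -1.21 and -0.0137, and all 17 members had a GC value. For camera the same trend was instead removed from each library's log2 CPM, and the list still passed (camera adjusted p = 5.24e-06). The median closest to 0 with 1 library left out was -0.6376. Both values argue against these explanations as the whole cause. An effect of UVA on collagen transcript levels stays open as a hypothesis; whether it acts on synthesis or decay of the transcripts was not tested.

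The rise of NRF2 targets with alpha-arbutin was set against the same trend, a single library and a chance low level in the UVA libraries. The corrected median was 0.1343 (quartiles 0.103 and 0.240; camera adjusted p = 1.15e-13), and the lowest median with 1 library left out was 0.1113, which argues against the trend and against 1 library as the whole cause. Against control cells the list's median was 0.2496, but UVA alone had already raised it by 0.14, so a chance low level in the UVA libraries cannot be told apart from an effect of alpha-arbutin. An induction of NRF2 targets by alpha-arbutin stays open as a hypothesis, as does a structure of the libraries apart from treatment. The split of UVA replicates 1 and 2 and co-treated replicate 1 against the other 3 libraries called 81 genes. Its lists included cholesterol synthesis, NRF2 targets and ATF4 targets (camera adjusted p = 4.03e-16, 4.24e-11 and 0.00243). What that structure is was not settled: 61 of the 81 were also called for UVA, against 29.3% of all genes, and 60 of these had the opposite sign, but over all genes r with the UVA effect was -0.0854. On the first principal component this split set the lowest irradiated libraries (8.55, 12.3 and 13.4) against the highest (13.7, 17.7 and 20.7). That component also separates control from irradiated libraries, but a difference in the extent of the UVA response was not tested. After group means were removed, same-numbered UVA and co-treated libraries had r of 0.0453, 0.0390 and 0.0756. Differently numbered ones ran from -0.0706 to 0.0259.

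The higher histone counts after UVA were set against reads divided differently between near-identical histone genes, a larger share of RNA without a poly(A) tail, and more cells in S phase. The summed histone CPM differed by 0.7276 on the log2 scale, 5.90 SD, which argues against a division of reads within the family. Other RNAs without a poly(A) tail had a median of 0.2916 with quartiles of -0.268 and 0.370, too wide to decide, so that RNA selection cannot be told apart from a change in histone transcripts. The DNA replication list had a median of 0.1076 and did not pass (adjusted p = 0.058), though it passed without UVA replicate 1. S phase therefore also cannot be told apart, and no count of cells by phase was used here.

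For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Every other split mixes the compared groups, so a real difference adds to the spread within its groups and lowers its count. A low count there does not show what libraries without an effect would give. The real split called 4142 genes for UVA against control, and the highest other split 0 (1 of 10 as large); for co-treated against control these were 3657 and 0 (1 of 10). For co-treated against UVA they were 5 and 81 (4 of 10 as large). Genes moved back were 3 and 77 (4 of 10), where each other split defines the UVA effect anew from its relabelled libraries and counts the larger of both labellings, so that the 77 are not a subset of the genes called for UVA. A split that calls many more genes than the real one points to a structure of the samples. Lists called were 21 against 10 for UVA (1 of 10), 10 against 14 for co-treated against UVA (2 of 10), and 18 against 11 for co-treated against control (1 of 10). The NRF2 median was 0.1427 against 0.1178 (1 of 10), and the collagen median was -0.7962 against 0.3556 in size (1 of 10).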
